A study of Mus musculus with 10 samples.

How the data were processed

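The series holds 10 RNA-seq libraries from the livers of C57BL/6 mice aged 4 months, 5 from mice fed standard chow and 5 from mice starved for 48 hours with free access to water. Each library is 1 mouse, numbered 1 to 5 within its group as in the sample titles. The libraries were made from total RNA with a strand-marking TruSeq kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.0, Bowtie2 2.0.0, HTSeq and edgeR 3.6.4, and the mouse genome build mm10. The HTSeq version, the gene annotation and the strand setting used for counting are not given in the sources used here. The deposited files hold whole-number read counts per gene symbol, not normalised, with 1 file per library and the unassigned-read tallies that HTSeq writes in the last rows. These tallies name no gene and stayed out of library sizes and tests. Of all tallied reads, the share that aligned to more than 1 place was 47.1% ± 0.780 (SD, n = 5) in fed and 42.9% ± 3.68 in starved libraries, and the share in no gene was 18.1% ± 2.46 and 20.1% ± 2.99. Reads that map equally to paralogs or pseudogenes were therefore left uncounted, and values of ribosomal protein, histone, guanylate-binding protein, cytochrome P450 and major urinary protein genes are uncertain to that extent. Without a stated strand setting, genes that overlap another gene on the opposite strand are uncertain as well.

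All further values were computed from the deposited counts in R 4.3.3. Genes with enough reads were kept with edgeR 4.0.16 (filterByExpr), which left 12796 of 23420 genes. Libraries were scaled by the trimmed mean of M values (TMM), and starved and fed livers were compared with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. The word "rose" or "fell" is used only for called genes, and levels are TMM-scaled CPM (read counts relative to library size), as mean ± SD over 5 libraries. Gene lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 42 lists, and again with the correlation estimated from these libraries. Fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, was an alternative. The 42 lists, 30 of pathways and functions and 12 of cell type markers, were fixed before the data were examined, together with the tests, the alternatives and the rule for the genes named. Beside the number of list members called over all genes, the number called when p-values were adjusted over the list alone is given.

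The genes named are the 8 with the highest and the 8 with the lowest log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between the groups, leaving out gene models that carry only a number. For each list they are up to 3 members that rose and 3 that fell with the largest change and at least 1 CPM in the higher group, or up to 2 of the most abundant members where none passed. A fixed set of metabolic genes and Alb is named whatever its values. Some genes that these rules select are left out of the text and of the figure of single genes. Coordinates are those of GENCODE's annotation of the same build (GRCm38, which is mm10), counted from 1. Of the gene rows, 98.2% matched that annotation by name or older symbol.

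The alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library totals alone as scaling, the DESeq2 1.42.0 Wald test, edgeR's likelihood ratio test and limma-voom, no low-count filter and a filter of 1 CPM in 5 libraries, a replicate block, a threshold of 0.01, libraries thinned to the smallest, and leaving out each library in turn. Leaving out starved libraries 2 and 4 together and removing trends on exon length and GC content were added after the data were seen. The fit was tested on simulated data for the comparison of 5 starved with 5 fed libraries, with 12796 genes of which 200 were changed. It recovered 7.5% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 90.9% of those changed 4-fold, with 13 calls among 12596 unchanged genes. With as many genes changed as the real comparison called, 4934, it recovered 57.9%, 89.3% and 98.2%, with 94 calls among 7862 unchanged genes, so the share of small changes missed depends on how many genes change. Genes were simulated independently and with the same spread in fed and starved libraries. The real starved libraries differed among themselves more than the fed libraries, so these rates need not hold for the real comparison. In a simulation of lists all 10 raised lists and 0 of 10 unchanged lists were called, but simulated genes vary independently, which real genes of a list do not.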

Results

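Gene expression was measured by RNA-seq in the livers of 5 fed and 5 starved mice, in a series on how the metabolic state regulates genes through the β-hydroxybutyrylation of histone lysines, a modification derived from the ketone body β-hydroxybutyrate. Starvation lasted 48 hours. Reads assigned to genes came to 26.5 ± 2.54 M per fed library (SD, n = 5; range 23.0 to 29.9 M) and 23.1 ± 4.10 M per starved library (range 18.2 to 28.1 M; exact two-sided permutation p = 0.159). No replicate pair matched within sampling noise, the chi-square per degree of freedom being 22.7 to 89.1 among fed and 11.9 to 284 among starved pairs.

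In starved liver, 24 of 25 genes of cholesterol synthesis and uptake and 19 of 25 of fatty acid and triglyceride synthesis fell. More genes rose than fell in amino acid catabolism (21 and 2 of 40), gluconeogenesis (9 and 0 of 17), peroxisomal oxidation (17 and 4 of 30), the proteasome (21 and 0 of 31) and ribosome biogenesis (25 and 0 of 32). Camera called all of these lists with its preset correlation, but with a correlation estimated from the libraries only the lipid lists and amino acid catabolism kept their call. Igfbp1, a secreted binding protein of insulin-like growth factors, rose the most, from 20.6 ± 8.76 to 2827 ± 3816 CPM (log2 fold change 7.10 ± 1.16 SE). Scd1, the desaturase that makes monounsaturated fatty acids, fell from 5876 ± 2460 to 268 ± 130 CPM (−4.46 ± 0.41). Of 12796 genes tested, 2379 were higher and 2555 lower in starved liver by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1693 changed at least 2-fold, 696 up and 997 down. The groups did not overlap in 29.9% of tested genes, where chance gives 0.79%. Starved libraries 2 and 4 stood apart from the other starved libraries, and without them 2647 genes were higher, 2705 lower and 1263 changed at least 2-fold. With library totals alone as scaling, which shifted the median of all genes by −0.15 (log2), 1490 genes were higher and 3490 lower, so that 29.9% of calls were higher in place of 48.2%.

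**Figure D1:**
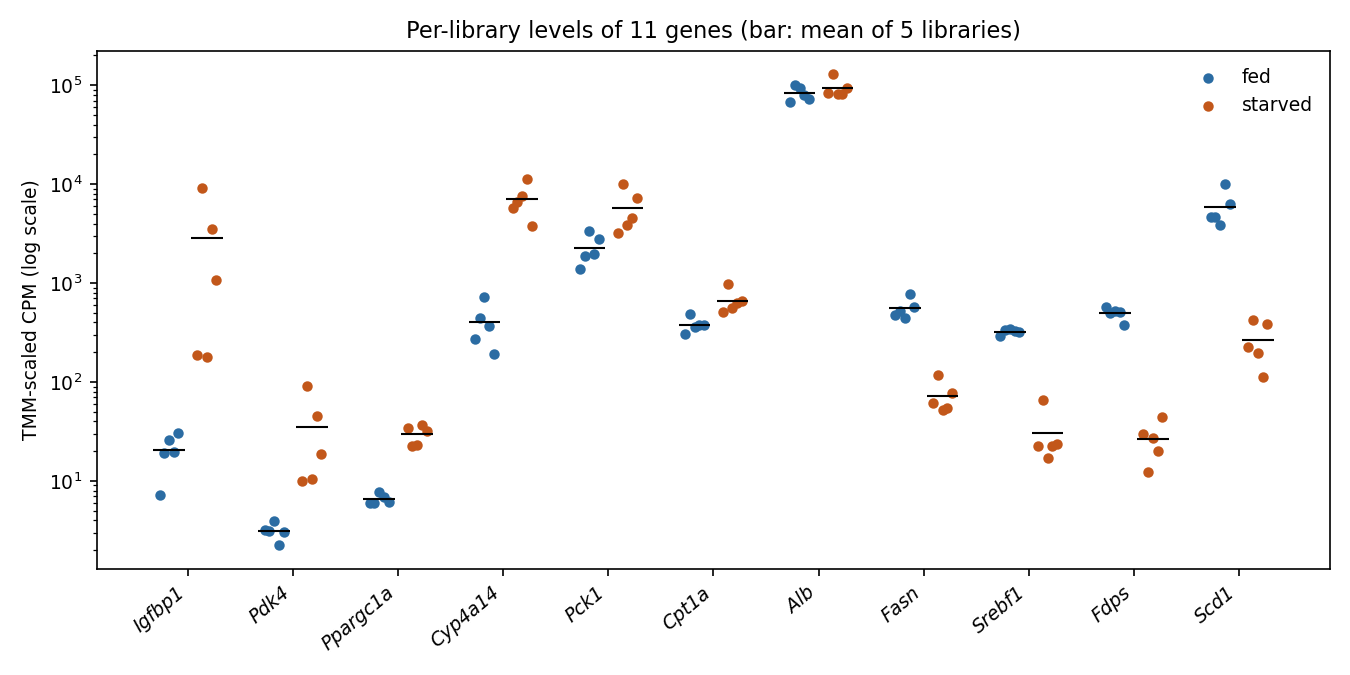
TMM-scaled CPM (log axis) of 11 genes in each of 5 fed (blue) and 5 starved (orange) liver libraries, points ordered by replicate within a group and bars at the group means. Scd1 fell from a mean of 5876 to 268 CPM, while the starved libraries spread widely in Igfbp1, from 178 to 9210 CPM.

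The other genes with the highest fold changes were Sult1e1, an estrogen sulfotransferase (log2 fold change 6.74 ± 0.69 SE, from 0.924 to 100.1 CPM), Ptgfr, the prostaglandin F receptor (5.97), Slc4a9, an anion exchanger (5.86), Cdkn1a, a cell cycle inhibitor (5.64), Adcy1, an adenylyl cyclase (5.37), Ddit4, an inhibitor of mTORC1 (5.16), and Dusp8, a phosphatase of MAP kinases (5.01). Starved libraries 2 and 4 carried much of these changes. Without them the log2 fold change was 4.55 for Igfbp1, 5.37 for Sult1e1, 2.68 for Ptgfr, 3.11 for Slc4a9, 4.30 for Cdkn1a, 1.41 for Adcy1, 3.05 for Ddit4 and 1.90 for Dusp8, and all 8 were still called. With all libraries, limma-voom did not call Adcy1. The strongest falls were those of Hsd3b5, a steroid dehydrogenase (−5.52 ± 0.53), and Gbp10, a guanylate-binding protein (−5.29). Both were near the detection floor in starved liver (0.131 and 0.225 CPM, from 5.75 and 8.52), so the size of these falls is uncertain. Next came Car3, a carbonic anhydrase (−4.94, from 1412 to 46.0 CPM), Scd1, and A1bg, a plasma glycoprotein (−4.27). Fdps and Mvd of the mevalonate pathway (−4.21 and −4.06) and Serpina6, the corticosteroid-binding globulin (−4.11), were the others. Alb, the albumin gene, stood at 82740 ± 14124 CPM in fed and 94215 ± 20087 CPM in starved liver (adjusted p = 0.49, edgeR's quasi-likelihood test) and was not called. Igfbp1 lies on chromosome 11 (7197782 to 7202546, mm10), Scd1 on chromosome 19 (44394455 to 44407879), Sult1e1 on chromosome 5 (87575969 to 87591594) and Hsd3b5 on chromosome 3 (98618634 to 98630252).

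Of 25 genes of cholesterol synthesis and uptake, 24 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 fold change of −2.49. Fdps (497 ± 71.8 to 26.8 ± 12 CPM) and Mvd were among the members with the largest falls. Of 25 genes of fatty acid and triglyceride synthesis, 19 fell and 1 rose (20 and 1 adjusted over the list alone; median −1.24). Besides Scd1, they included Aacs, which activates acetoacetate for lipid synthesis (−3.62 ± 0.27), Srebf1, the transcription factor of lipogenic genes (−3.41 ± 0.34, from 323 ± 20 to 30.4 ± 20.2 CPM), and Fasn, the fatty acid synthase (−2.94 ± 0.25). Lpin1, a phosphatidate phosphatase that also acts as a transcriptional coactivator, was the member that rose (1.83 ± 0.28). Srebf1 overlaps Rai1 on the opposite strand. Both lists were lower than other genes by camera (adjusted p = 1.6e-42 and 1.3e-15), also with an estimated correlation (adjusted p = 0.0272 and 0.0487).

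Among 30 genes of peroxisomal oxidation and targets of PPARA, the fatty acid receptor of liver, 17 rose and 4 fell (19 and 4 adjusted over the list alone; median 0.68). Cyp4a14 and Cyp4a10, fatty acid ω-hydroxylases, rose from 400 ± 203 to 7012 ± 2813 CPM and from 288 ± 126 to 4185 ± 1434 CPM, and Pdk4, the kinase that shuts down pyruvate dehydrogenase, by a log2 fold change of 3.50 ± 0.60 (2.08 without starved libraries 2 and 4). Fabp1, a fatty acid carrier (−2.07 ± 0.40), Acot3, a peroxisomal thioesterase (−1.66 ± 0.42), and Ppara itself (−1.20 ± 0.21) fell. The list was higher by camera (adjusted p = 9.6e-06; adjusted p = 0.286 with an estimated correlation). Of 22 genes of mitochondrial fatty acid oxidation, 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.32), and without starved libraries 2 and 4, 15 rose and 0 fell. Acadm, a medium-chain dehydrogenase (0.83 ± 0.16), Cpt1a, the entry step of fatty acids into mitochondria (0.81 ± 0.18), and Hadhb, of the trifunctional protein (0.67 ± 0.15), rose. This list's camera call (adjusted p = 0.00673) was lost with an estimated correlation (adjusted p = 0.514 with an estimated correlation).

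Of 6 ketogenesis genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.532). Slc16a1, a transporter of lactate and ketone bodies, rose (0.53 ± 0.18), and this call was lost without fed library 1 (0.44), 4 (0.46) or 5 (0.51) and without starved libraries 2 and 4 together (0.42), and also with library totals alone and without length and GC trends. Bdh1, which interconverts acetoacetate and β-hydroxybutyrate, fell (−1.61 ± 0.47, from 262 ± 44.3 to 86.0 ± 57.4 CPM), and by −1.04 without starved libraries 2 and 4. Fgf21, a fasting hormone of the liver, was near the detection floor at 0.792 ± 0.392 and 2.97 ± 2.83 CPM and was not called (1.87 ± 0.77, adjusted p = 0.072, edgeR's quasi-likelihood test), but was called without starved library 2 (2.18, adjusted p = 0.00553) and without starved libraries 2 and 4 (2.52).

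Among 17 gluconeogenesis genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.61). Got1, the cytosolic aspartate aminotransferase (3.19 ± 0.47, and 2.13 without starved libraries 2 and 4), Ppargc1a, a transcriptional coactivator of fasting genes (2.18 ± 0.16, from 6.56 ± 0.753 to 29.7 ± 6.51 CPM), Gpt2, an alanine aminotransferase (1.43 ± 0.27), and Pck1, which makes phosphoenolpyruvate (1.34 ± 0.33), rose. G6pc, the glucose-6-phosphatase, stood at 198 ± 104 and 459 ± 313 CPM (1.21 ± 0.50, adjusted p = 0.073, edgeR's quasi-likelihood test) and was not called. It was called by DESeq2's Wald test (adjusted p = 0.0248), by edgeR's likelihood ratio test (adjusted p = 0.0368), with a replicate block in edgeR (adjusted p = 0.0329) and without starved library 3 (1.42). Of 21 genes of glycolysis and glycogen storage, 5 rose and 9 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.145). Pklr, the liver pyruvate kinase, which overlaps Hcn3 on the opposite strand (−3.09 ± 0.37), and Pygl, the glycogen phosphorylase (−1.28 ± 0.22), fell. Ppp1r3g, a glycogen-targeting phosphatase subunit, rose (6.11 ± 1.36, and 2.35 without starved libraries 2 and 4), but was not called by limma-voom. The gluconeogenesis list was higher by camera (adjusted p = 3.6e-05; adjusted p = 0.0969 with an estimated correlation).

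Of 40 genes of amino acid catabolism, 21 rose and 2 fell (21 and 2 adjusted over the list alone; median 0.48), and the list was higher by camera (adjusted p = 2.4e-07), also with an estimated correlation (adjusted p = 0.0487). Besides Got1, Sdsl, a serine dehydratase (2.52 ± 0.37), and Tat, the tyrosine aminotransferase (2.38 ± 0.41), rose the most (1.70 and 1.64 without starved libraries 2 and 4), while Haao of tryptophan breakdown (−1.04 ± 0.21) and Aldh4a1 of proline breakdown (−0.87 ± 0.13) fell. Of 9 urea cycle genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone). Asl, the argininosuccinate lyase, rose from 604 ± 87.4 to 2560 ± 462 CPM, Cps1, the entry enzyme, by 1.63 ± 0.30 and Arg1, the arginase, by 1.43 ± 0.13 on the log2 scale, and Glud1, the glutamate dehydrogenase, fell (−0.50 ± 0.13). Without starved libraries 2 and 4 Cps1 rose by 1.07. The urea cycle list was higher by camera (adjusted p = 0.000565; adjusted p = 0.0952 with an estimated correlation). Among 13 periportal hepatocyte markers, 7 rose and 3 fell (8 and 3 adjusted over the list alone; median 1.23). As fixed, this list shares Cps1, Arg1, Ass1, Gls2, Pck1, Hal and Sds with the urea cycle, gluconeogenesis and amino acid lists. It therefore largely recounts those results. Agxt2l1, a phospho-lyase outside those lists, rose the most (3.11 ± 0.60, and 1.44 without starved libraries 2 and 4). Ctsc (−1.15 ± 0.25), Aldh1b1 (−0.87 ± 0.27) and Cyp2f2 (−0.59 ± 0.19), also outside those lists, fell. The call of Cyp2f2 was lost without starved libraries 2 and 4, and that of Aldh1b1 without fed library 2 or 4. The list was higher by camera (adjusted p = 0.00222; adjusted p = 0.236 with an estimated correlation). Of 14 pericentral markers, 1 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.155), among the latter Lect2, a secreted protein (−1.61 ± 0.34), and Cyp1a2, a cytochrome P450 (−1.58 ± 0.44). Cyp1a2 fell by −1.02 without starved libraries 2 and 4.

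**Figure D2:**
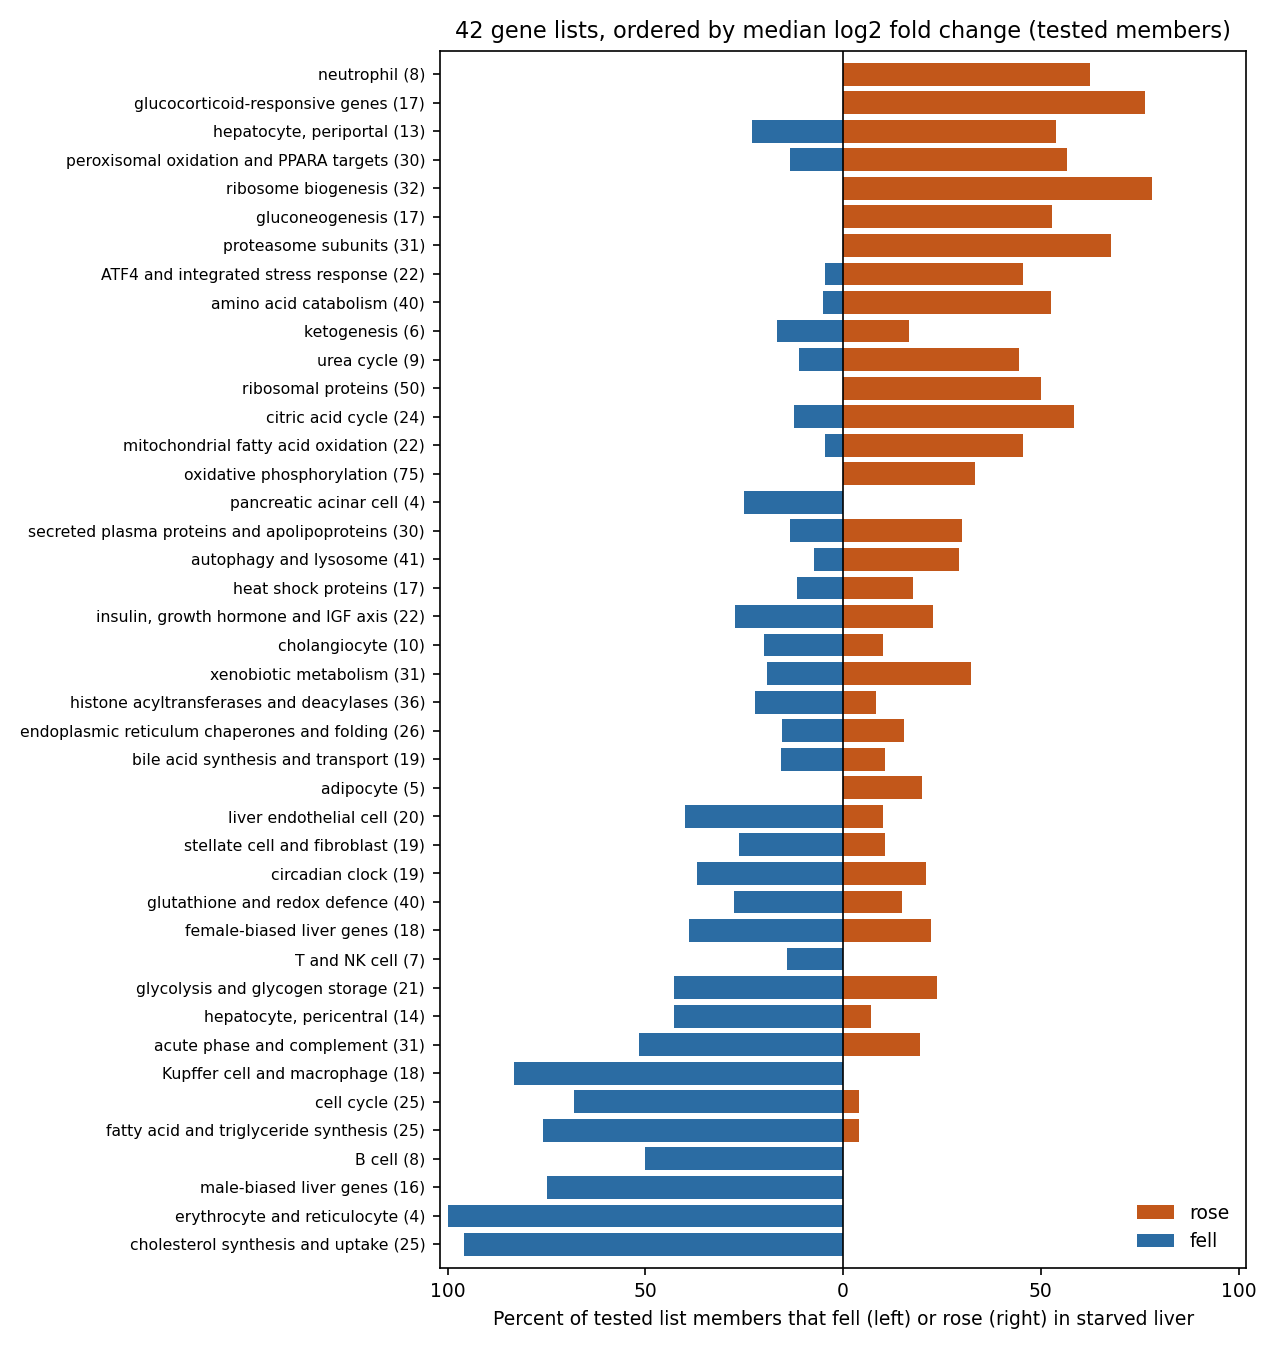
Percent of the tested members of each of 42 gene lists that rose (orange, right) or fell (blue, left) in starved liver at an adjusted p under 0.05, with the number tested in parentheses and lists ordered by median log2 fold change. Of cholesterol synthesis genes 24 of 25 fell, and of ribosome biogenesis genes 25 of 32 rose.

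Of 32 genes of ribosome biogenesis, 25 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.62), including Myc, a growth-promoting transcription factor (3.38 ± 0.70, and 1.64 without starved libraries 2 and 4), and Rrp12, of ribosomal RNA processing (1.64 ± 0.32, and 0.98 without them). Of 31 proteasome subunits, 21 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.52), such as Psmd4 (0.99 ± 0.14) and Psmc1 (0.88 ± 0.10). Of 50 ribosomal protein genes, 25 rose and 0 fell (34 and 0 adjusted over the list alone; median 0.37). Rps18 (0.66 ± 0.19) and Rps25 (0.60 ± 0.15) rose, and both calls were lost with library totals alone. Camera called the 3 lists (adjusted p = 1.5e-07, 2.3e-07 and 1.2e-06), but not with correlations estimated from the libraries (adjusted p = 0.35, 0.451 and 0.595 with an estimated correlation). Of 41 autophagy and lysosome genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone), led by Ctsl, a lysosomal protease (2.16 ± 0.39), and Wipi1, of autophagosome formation (1.70 ± 0.29), which rose by 1.28 and 1.12 without starved libraries 2 and 4, while Ulk2, an autophagy kinase, fell (−1.47 ± 0.16). Its camera call (adjusted p = 0.0462; adjusted p = 0.35 with an estimated correlation) was lost with library totals alone (adjusted p = 0.0788) and with a filter of 1 CPM in 5 libraries (0.0576). It was also lost without fed library 1 (0.0698) or 3 (0.0648) and without starved library 5 (0.0566).

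Of 75 oxidative phosphorylation genes, 25 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.25), with Cycs, cytochrome c, highest (0.93 ± 0.14), and without starved libraries 2 and 4, 43 rose. Of 24 citric acid cycle genes, 14 rose and 3 fell (14 and 4 adjusted over the list alone; median 0.35). Fh1, the fumarase, rose (1.94 ± 0.22), and Idh1, the cytosolic isocitrate dehydrogenase, fell (−1.68 ± 0.28). Camera called both lists (adjusted p = 0.000196 and 0.00264; adjusted p = 0.663 and 0.219 with an estimated correlation). Of 22 genes of the ATF4 and integrated stress response, 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.113), and 6 rose and 2 fell without starved libraries 2 and 4. The list passed camera with library totals alone (adjusted p = 0.0356) and without starved library 1 (0.0405) or 3 (0.0495). Sesn2, a stress-induced regulator of mTORC1, rose (2.27 ± 0.61, and 0.93 without starved libraries 2 and 4), but was not called by limma-voom. The call of Atf3, a stress-induced transcription factor (3.11 ± 1.01), was lost without starved library 2 (0.61), without any single fed library, with limma-voom and with a replicate block. Of 26 endoplasmic reticulum chaperones, 4 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.895, with a median of −0.11 but a test direction up), Dnajb9 (0.96 ± 0.10) and Pdia6 (−0.81 ± 0.16) among them. Of 17 heat shock protein genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.532). Hspb1 rose (1.08 ± 0.20) and Cryab fell (−0.98 ± 0.18).

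Of 17 glucocorticoid-responsive genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.85), led by Ddit4 and by Mt2 and Mt1, the metallothioneins (3.69 ± 0.79 and 3.06 ± 0.52). Without starved libraries 2 and 4 the median was 0.98, with 11 genes higher and 1 lower, and Mt2 and Mt1 rose by 1.85 and 2.03. The list was higher by camera (adjusted p = 8.3e-07; adjusted p = 0.305 with an estimated correlation). In the insulin, growth hormone and IGF axis, 5 of 22 genes rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.895). Lepr, the leptin receptor, rose (4.86 ± 0.94, and 2.21 without starved libraries 2 and 4) with Igfbp1 and Irs2, an insulin receptor substrate (1.8 ± 0.51, and 0.73 without these libraries), while Ghr, the growth hormone receptor (−1.8 ± 0.29), Igfals, which carries IGF in plasma (−1.69 ± 0.41), and Igf1 (−0.73 ± 0.18, from 545 ± 63.7 to 328 ± 83.6 CPM) fell. The median of this list, 0.05, turned to −0.11 with library totals alone, and limma-voom did not call Irs2. Of 19 circadian clock genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.329). Arntl, an activator of the clock, rose (3.61 ± 0.38, and 3.004 without starved libraries 2 and 4, from 1.73 ± 0.459 to 21.3 ± 12.8 CPM), and Dbp, a clock output factor that overlaps Sphk2 on the opposite strand (−3.20 ± 0.34), and Per3, a clock repressor (−2.14 ± 0.41), fell. This list passed camera without starved library 2 (adjusted p = 0.0127) and without starved libraries 2 and 4 (adjusted p = 0.000637), in the downward direction.

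Of 31 acute phase and complement genes, 6 rose and 16 fell (6 and 16 adjusted over the list alone; camera adjusted p = 0.123). This list passed camera in the downward direction with a replicate block (adjusted p = 0.0413) and without length and GC trends (adjusted p = 0.0417). C8a of the complement attack complex fell (−2.40 ± 0.27), and Serpina3n, a protease inhibitor, rose (1.11 ± 0.24). Of 30 secreted plasma protein genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0816). Apoa4, an apolipoprotein, rose from 256 ± 35.8 to 4475 ± 2082 CPM, and Ttr, the transthyretin gene, fell (−0.88 ± 0.22). The plasma protein list passed camera, upward, with a replicate block (adjusted p = 0.0472) and with no low-count filter (0.0465). It also passed without fed library 2 (adjusted p = 0.0376), without starved library 4 (0.0276) and without starved libraries 2 and 4 (0.0342). Of 40 glutathione and redox genes, 6 rose and 11 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.193). Srxn1, a sulfiredoxin, rose (1.58 ± 0.25), and Gstm3, a glutathione transferase, fell (−2.59 ± 0.42). Of 31 genes of xenobiotic metabolism, 10 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.123). Cyp2b10, a drug-inducible cytochrome P450, rose from 24.6 ± 10.4 to 616 ± 439 CPM (log2 fold change 4.65, and 3.67 without starved libraries 2 and 4) and Ugt2b1, a glucuronosyltransferase, fell (−1.23 ± 0.24). The median of this list, 0.003, turned to −0.144 with library totals alone, and the list passed camera without starved libraries 2 and 4 (adjusted p = 0.0122). Of 19 bile acid genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.518). Cyp8b1, which sets the share of cholic acid, rose (2.46 ± 0.26), and Slco1a1, an organic anion carrier (−4.05 ± 0.34), and Abcb11, the bile salt export pump (−1.05 ± 0.23), fell.

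Of 36 histone acyltransferases, deacylases and related enzymes, 3 rose and 8 fell (3 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.329), though fry called it lower (adjusted p = 0.00127). Acss2, which makes acetyl-CoA from acetate and overlaps Ggt7 and Gss on the opposite strand, fell (−2.10 ± 0.24, from 304 ± 108 to 71.0 ± 14.4 CPM), as did the deacetylase Hdac11 (−1.26 ± 0.19), while the acetyltransferases Kat5 (0.58 ± 0.15) and Kat2a (0.45 ± 0.14) rose. Without starved libraries 2 and 4 Kat5 rose by 0.35, and the call of Kat2a was lost with library totals alone. Of 25 cell cycle genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone; median −1.05). Top2a, the DNA topoisomerase of dividing cells (−3.92 ± 0.25), and Mki67, a proliferation marker (−2.87 ± 0.26), fell from low levels of 3.52 ± 0.803 and 3.21 ± 0.388 CPM, and Cdkn1a was the member that rose. The list was lower by camera (adjusted p = 1.0e-06; adjusted p = 0.133 with an estimated correlation).

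Markers of several other cell types were lower in starved liver. Of 18 markers of Kupffer cells and macrophages, 15 fell and 0 rose (15 and 0 adjusted over the list alone; median −0.76), including Emr1, which encodes F4/80 (43.6 ± 14.4 to 15.3 ± 3.61 CPM), and Cd5l, a secreted macrophage protein (−1.29 ± 0.33). Of 8 B cell markers, 4 fell and 0 rose (7 and 0 adjusted over the list alone; median −1.28), the antigen presentation genes H2-Aa, H2-Ab1 and Cd74 among them. Without starved libraries 2 and 4 these 3 were the only B cell markers that fell (median of the list −1.02). Of 4 erythrocyte markers 4 fell (4 adjusted over the list alone), such as Alas2 of haem synthesis (−1.38 ± 0.28). Of 8 neutrophil markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.90), with S100a9, a calcium-binding protein, at 1.34 ± 0.516 in fed and 5.47 ± 3.20 CPM in starved liver. Starved library 5 did not share this rise. Its median difference from the fed mean over these markers was 0.06 (log2), against 1.36 to 2.34 in the other starved libraries, and its S100a9 level was 0.869 CPM. Camera called these 4 lists (adjusted p = 6.8e-06, 0.000337, 0.00184 and 0.00264; adjusted p = 0.35, 0.305, 0.305 and 0.35 with an estimated correlation). Besides these and the periportal list, no marker list passed camera. Of 20 endothelial markers, 2 rose, led by Lyve1 (1.74 ± 0.21), and 8 fell (2 and 8 adjusted over the list alone; adjusted p = 0.222). Of 19 stellate cell and fibroblast markers, 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.135). The collagen gene Col3a1 fell the most (−2.32 ± 0.23). Of 10 cholangiocyte markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.899), with a median of 0.04 and a mean of −0.08, and that median was −0.12 with library totals alone. Of 7 T and NK cell markers, 1 fell and 0 rose (1 and 0 adjusted over the list alone; adjusted p = 0.428). Of 5 adipocyte markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.557), with a median of −0.27 but a test direction up. Of 4 pancreatic acinar markers 1 fell and 0 rose (1 and 0 adjusted over the list alone; adjusted p = 0.575), with a median of 0.22 and a mean of −0.14.

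The mice are labelled male. In all 10 libraries, Xist, the RNA of the inactive X chromosome, had between 2898 and 11569 reads, while the Y-linked genes Ddx3y, Eif2s3y and Uty had 0 reads and Kdm5d had 1 read in total. A count of 0 allows at most 0.165 CPM in any library, for counting error. Of 45 Y-linked gene rows, 2 held a read, with 23 reads over all libraries and 22 of them in Uba1y. Cyp4a12a, a cytochrome P450 of male liver, had at most 6 reads, and Cyp2b9, enriched in female liver, had 298 to 503 CPM. Of 16 male-biased liver genes tested, 12 fell and 0 rose in starved liver (13 and 0 adjusted over the list alone; median −1.35), with Hsd3b5, Slco1a1 and Selenbp2, a selenium-binding protein (−3.74 ± 0.51), lowest. The list was lower by camera (adjusted p = 2.0e-07; adjusted p = 0.286 with an estimated correlation). Of 18 female-biased genes, 4 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.861). Cyp2b10 and Cyp17a1, a steroid hydroxylase (1.97 ± 0.15), rose, and Slc22a27, an anion carrier, fell (−1.83 ± 0.27).

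The starved livers differed among themselves more than the fed livers did. On the principal component that held 65.1% of the variance, the fed libraries lay between −43.4 and −39.7, starved libraries 1, 3 and 5 between 17.7 and 19.0, library 4 at 63.9 and library 2 at 90.1. Igfbp1 stood at 186, 9210, 178, 3487 and 1074 CPM in starved libraries 1 to 5, against 7.27 to 30.6 CPM in fed libraries. Without starved libraries 2 and 4, 24 lists passed camera in place of 21. All 25 genes of cholesterol synthesis, 20 of 25 of fatty acid and triglyceride synthesis and 15 of 18 macrophage markers fell there, and 26 of 40 amino acid catabolism genes, 28 of 31 proteasome subunits and 23 of 32 ribosome biogenesis genes rose.

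**Figure D3:**
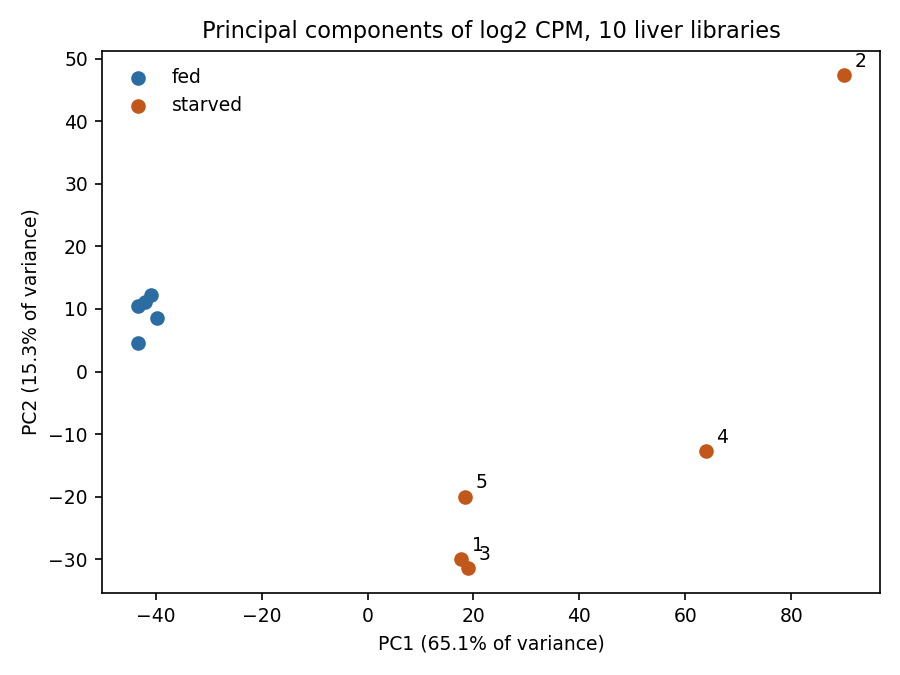
Scores of the 10 libraries (fed blue, starved orange with replicate numbers) on the principal components with 65.1% (horizontal) and 15.3% (vertical) of the variance of log2 CPM. The fed libraries lie together, and starved libraries 4 and 2 lie beyond the other starved libraries at 63.9 and 90.1.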

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

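The percentage for starved library 4 alone, the spread around the bound of 65%, the neutrophil medians against libraries 1 and 3, the plasma protein values and the list permutations were chosen after the results were seen. The remaining bounds were set before their values were known.

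Among 386 groups of 5 libraries (the named genes and library measures), 29 held a library whose gap to its neighbour took up most of the group's range. Independent, normally distributed values would give about 1 in 20 groups, or 19.3. All but that of Rps27 were highest values, as skewed values also give, and the groups share the same mice. The 19.3 is therefore only a rough guide for these 29 groups. Starved library 2 was the highest of its group in 14 of them, at 124 CPM for Cdkn1a, 31.2 for Dusp8, 66.2 for Srebf1, 129000 for Alb, 103 for Slc16a1, 304 for Ppp1r3g, 206 for Per1, 55.8 for Bhlhe40, 105 for Irs2, 68.5 for Atf3, 80.3 for Sesn2, 1660 for Herpud1, 1870 for Mt2 and 494 for Dcn. Starved library 4 was highest at 60.4 CPM for Ptgfr, 257 for Aldoa and 158 for Srxn1, and starved library 5 at 1230 for Glud1 and 6.03 for Selenbp2. Among fed libraries, library 4 was highest at 246 CPM for Aacs, 17.2 for Hmox1, 6.68 for Cyp2c55 and 21.2 for Onecut1. Fed library 2 was highest at 105 CPM for Cs, 34.8 for Dnajb9 and 406 for Ugt2b1 and lowest at 0.133 for Rps27, fed library 5 highest at 680 for Rbp4 and fed library 1 at 1.93 for Ccnb1.

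Starved libraries 2 and 4 departed from the mean of starved libraries 1, 3 and 5 by over 1 (log2) in 2929 and 874 genes. They also stood apart in how reads were assigned, with 38.6 and 40.7% of reads aligned to more than 1 place against 43.4 to 48.4% in the other starved libraries, and 41.75 and 39.98% assigned to genes against 31.25 to 34.74%. Ambiguous reads came to 0.79 and 0.69%, against 0.50 to 0.58%. Whether a difference in library preparation lies behind this was not tested and stays open. Exon length and GC bias is argued against, since both slopes on the other starved livers' response stayed above 1, at 1.278 and 1.198, once those trends were removed. A larger extent of the shared response met its bound of 65% in library 4, where 81.1% of departing genes extended it, and in library 2 the 63.5% fell short by less than 2 binomial SE (0.89 each, over genes that are not independent). The slope of library 2 on the other starved livers' response was 1.27, so this explanation stays open for both libraries together. Other cell types stay open, since neutrophil markers were raised by medians of at least 1.08 in both, as their bound required. That rests on starved library 5, which was low in these markers, since against libraries 1 and 3 alone the medians were 0.64 in library 2 and 1.01 in library 4. S100a8 and S100a9 reached at most 9.39 CPM. For the 360 genes lower in both libraries, dilution by a larger share of other cells is argued against. The 30 plasma protein transcripts, which such dilution would lower too, had a median departure no lower than −0.23. A smaller share of other cells would not lower those transcripts, so this test cannot address it, and it stays open. How far each mouse's own metabolic state differed was not tested.

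In 100 of the splits of the 10 libraries into 5 and 5, only the real split gave as many genes higher (1 of 100, 2379 against at most 0 in the others), lower (1 of 100, 2555 against 0) or changed at least 2-fold (1 of 100, 1693 against 0). Chance is argued against for these counts, as far as this number of splits can show. Every other split mixed fed and starved livers on both sides, which widens the spread within each side and makes calls unlikely. For the number of lists past camera with its preset correlation, 11 of 100 splits gave as many (21 in the real split, at most 23 in another). The splits with 23 lists exchanged only 1 library per side and so kept much of the difference between fed and starved livers. Some splits that exchanged 2 per side reached 21 as well. Chance is therefore not excluded for the number of lists, and this test cannot decide the question. After this was seen, the mean log2 difference of each list was set against all 126 splits by an exact two-sided permutation test, and 27 of 42 lists passed at an adjusted p under 0.05, 20 of them among the 21 of camera. Oxidative phosphorylation did not (adjusted p = 0.104), and the smallest p these splits can give is 0.00794. This permutation test does not compare a list with other genes, and by the planned tests the count was 21 with camera, 3 with an estimated correlation and 29 with fry.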

How the results depend on the processing

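Leaving out starved libraries 2 and 4 and removing length and GC trends were alternatives chosen after the data were seen. The counts of genes and lists stayed within 1.5 times of those reported under the alternatives run, with these exceptions. Library totals alone gave 1490 genes higher. A threshold of 0.01 gave 1272 higher and 1526 lower, by its own construction. Camera with an estimated correlation called 3 lists. Leaving out each library in turn gave 1868 to 2766 genes higher, 2043 to 2847 lower, 1495 to 1960 changed at least 2-fold and 20 to 22 lists. DESeq2's Wald test called 2846 higher and 2678 lower. Removing length and GC trends called 2734 and 2487. With the replicate number as a block (replicate block), 2029 genes were higher, 2381 lower, 1636 changed at least 2-fold and 23 lists passed. The fit with the group alone was fixed beforehand as the main one, since the labels do not say that replicate numbers mark pairs. With group means removed, same-numbered fed and starved libraries correlated at 0.198, 0.067, −0.012, −0.045 and −0.029. Only fed library 1 correlated best with the starved library of its own number. The treatment protocol speaks of 5 pairs of mice, which could mean pairs by number, and the labels do not settle this. Fry called 9 lists that camera did not, ATF4, plasma protein, acute phase and histone enzyme genes among them, and did not call oxidative phosphorylation. Limma-voom did not call Adcy1, Atf3, Irs2, Ppp1r3g and Sesn2. No named gene reversed under any alternative. The directions that reversed were all of lists without a call, and the cause was not tested. Adjusted p-values of the reversed tests were 0.933 with library totals and 0.88 without starved libraries 2 and 4 for female-biased genes. For endoplasmic reticulum chaperones they were 0.96 with limma-voom, 0.989 without length and GC trends and 0.887 with fry, and 0.731 to 0.994 on leaving out single libraries (0.566 to 0.994 with those that did not reverse). For cholangiocyte markers they were 0.948 with no low-count filter, 0.887 with fry and 0.921 to 0.973 on leaving out single libraries (0.735 to 0.989 with those that did not reverse). For the IGF axis they were 0.621 without starved libraries 2 and 4, 0.887 with fry and 0.924 to 0.98 on leaving out single libraries (0.549 to 0.98 with those that did not reverse). With no low-count filter they were 0.948 for adipocyte and 0.408 for pancreatic acinar markers. Thinned to the smallest library, 2239 genes were higher and 2396 lower, so depth sets part of the count.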

Other observations

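The gene families below and both tests on the sex of the animals were chosen after the data were seen. The bounds of both tests on macrophage markers were set before their values were known.

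Of 18 gene families counted, those below are the 11 that camera called with its preset correlation. Chosen after the fold changes were seen, they are described by counts alone, since a test on the same fold changes adds no support. With an estimated correlation 10 of the 11 lost that call, all but the guanylate-binding proteins. Of 11 guanylate-binding protein genes, which act in defence against intracellular pathogens, 10 fell and 0 rose (median log2 fold change −1.82), such as Gbp6, from 10.3 ± 1.83 to 1.65 ± 0.506 CPM, and Gbp3. Of 36 immunity-related GTPases and interferon-induced genes, 26 fell and 0 rose (median −1.21), among them Irf7, a transcription factor of the interferon response, from 43.4 ± 10.3 to 11.5 ± 3.73 CPM. Of 22 MHC genes, 11 fell and 0 rose (median −0.69). Without starved libraries 2 and 4, 11, 29 and 10 genes of these families fell. Markers of cells that express such genes were lower as well, by medians of −0.76 for macrophages and −1.28 for B cells. H2-Aa, H2-Ab1 and Cd74 are themselves B cell markers here, and the only ones that fell without starved libraries 2 and 4. Fewer such cells and lower expression within cells were not separated.

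Of 41 core and linker histone genes, 27 fell and 5 rose (median −0.93), and 28 fell without starved libraries 2 and 4. Hist1h1c, a linker histone gene, rose (2.19 ± 0.65), with 798 CPM in starved library 2. Of 9 small nucleolar RNA host genes, 8 rose and 0 fell (median 1.2), and of 9 subunits of the chaperonin TRiC 6 rose and 0 fell (median 0.44). Of 55 genes whose symbols begin with Eif, 32 rose and 4 fell (median 0.36). These include translation initiation factors, but the 4 that fell, Eif2c1, Eif2ak2, Eif2c3 and Eif4ebp2, are not initiation factors themselves. Of 11 major urinary protein genes 7 fell and 0 rose (median −0.83), of 26 collagen genes 11 fell and 2 rose (median −0.50), of 45 spliceosome genes 15 rose and 0 fell (median 0.25) and of 76 mitochondrial ribosomal protein genes 18 rose and 3 fell (median 0.10). Without starved libraries 2 and 4 the medians were −0.52 for major urinary proteins and 0.16 for spliceosome genes, and 34 mitochondrial ribosomal protein genes rose (median 0.23).

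The labels call the mice male, while Xist was abundant and Y-linked genes were nearly silent in every library. An alignment index without the Y chromosome is argued against by the 23 reads in its rows, although 22 of them lie in Uba1y. A candidate explanation is that the animals were female, since the lowest Xist count of any library was 2898 and Ddx3y, Eif2s3y, Kdm5d and Uty summed to under 3 reads in each library. This was tested on the transcripts in which the pattern was seen, and it leaves the comparison of fed with starved livers in place, since both groups show it.

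Macrophage markers were lower in starved liver by a median of −0.76. A larger hepatocyte share of the RNA, which would lower the markers of other liver cells alike, is argued against as the whole cause, since the median of 49 endothelial, stellate and cholangiocyte markers was −0.25 (two-sided permutation p = 0.00193 over genes, which are not independent). Starved libraries 2 and 4 alone are argued against too, since 15 of 18 markers fell without them. Fewer macrophages in starved liver and lower transcript levels within them may both lie behind this, and the libraries hold no measure that separates them.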
